A study of Homo sapiens with 16 samples.

How the data were processed

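Gene expression was measured by RNA sequencing in NCI-H1688, a human small cell lung cancer line, after 24 h of culture with a drug or without one. There were 16 libraries in 8 groups of 2, and the labels describe the duplicates as biological. The groups were control cells, sanguinarine chloride at 1 µM, cepharanthine at 3 µM, evodiamine at 3 µM, the BET bromodomain inhibitor JQ1 at 28 µM, the histone deacetylase inhibitor panobinostat at 60 nM, and sanguinarine combined with either JQ1 or panobinostat at the doses used alone. The control libraries are labelled untreated, whereas the series design describes a DMSO control. Per the labels, RNA was purified on poly(A), so transcripts without a tail were read poorly.

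The deposited data were 2 tables of 44591 gene rows, of which 19233 were protein-coding and 33861 carried an NCBI gene number. The deposited counts are whole numbers of reads per gene per library, per the file headers and the values themselves. The deposited RPKM values are those counts scaled to the length of the gene model and the total of the library, and RPKM computed here from the counts differed from them by at most a relative 2.0e-13. The series design states that the authors mapped reads with STAR 2.5.1 to GRCh38, used an annotation named GENCODE vM21 (a name from the mouse series) and tested expression with DESeq2. The counting tool is not given in the sources used here. Gene positions in the tables ran past the end of their GRCh38 chromosome for 534 genes, and only 14.9% of 18301 protein-coding symbols overlapped the gene of the same symbol in GENCODE 44, so no coordinates are printed. Gene symbols stored as dates were restored for 27 genes.

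The first table held the control and the alkaloids given alone, and the second held JQ1, panobinostat and both combinations. Control libraries occurred only in the first table. In comparisons of second-table groups with the control or with sanguinarine alone, the table and the drug therefore cannot be told apart. The tables were also counted differently over overlapping genes. There were 164 genes with no counts in the first table and at least 1 CPM (the usual unit of counts scaled to library size) in every library of the second. All 164 overlapped another gene by position, against 55.8% of the 17521 genes that reached 1 CPM in some library, and 0 genes showed the reverse. In the second table the genes MTPN and LUZP6, which share sequence, held the same count in 8 of 8 libraries. Library titles beginning with S- in the second table carry the label of JQ1 or panobinostat alone, and titles without it carry the combination labels. Groups follow the treatment labels.

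Depth was 39996881 to 64060919 counted reads per library. A gene with no reads in a library could be present at up to 0.0468 to 0.075 CPM, taking 3 counts as the floor. For a group in which every library had 0 counts, the fold is given as a lower bound from 3 counts over the group. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The intervals of fold changes come from the model below, whose dispersion also takes in the spread between duplicates, pooled over all groups. They therefore do not follow the spread of the groups compared. Duplicates of sanguinarine with panobinostat differed more than those of any other group, so intervals of contrasts with that group may be too narrow.

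Counts of all 16 libraries were fitted in a single edgeR 4.0.16 quasi-likelihood model with a term per group, TMM scaling and the filterByExpr filter, which left 22263 genes. P values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called changed. Every adjusted p for a gene comes from this edgeR model, or, where a library is named as left out, from a refit without it. Fold changes are given on the log2 scale with an approximate standard error (±) or 95% interval, and group levels as mean CPM ± SD with n = 2. That error is the absolute log2 change divided by the square root of the quasi-likelihood F statistic, and the interval is built from it. It is unreliable, and may be too small, for large folds against a group with few or no counts. There were 17 comparisons, of which 16 were fixed before the data were examined. The comparison of JQ1 with panobinostat was added after the difference between the tables was seen. The interaction of sanguinarine with a partner drug was the change from partner to combination minus the change from control to sanguinarine, in which an additive offset between the tables on the log2 scale cancels.

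A set of 30 gene lists, also fixed before the data were examined, was tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Every adjusted p for a list comes from camera, and the test was repeated with the correlation estimated from the data. Some lists share members and are not separate evidence. HIST1H1C, HIST1H2BD, HIST1H2BK and HIST2H2BE are in both the BET inhibitor response and the polyadenylated histone lists. NQO1 is in both the NRF2 and the aryl hydrocarbon receptor lists. Genes of a list were counted as higher, lower or not passing from the gene test adjusted over all genes, and again adjusted over the list alone. Correlations of fold changes were computed across genes, which are not independent replicates. Overlaps between the alkaloids, which share the control libraries, were set beside 20 simulations of groups that did not differ from the control.

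Genes named in the text followed a rule written beforehand. It took the 6 largest rises and 6 largest falls per comparison (5 for interactions) among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. It added up to 4 members of each passing list and a fixed set of genes of this tumour type and these drugs. For comparisons across the tables, the 6 largest changes each way among genes that overlap no other gene were added after their values were seen. Some genes named by the rule were left out for space, among them most whose call depended on a single library, and a few are not reported here.

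Recovery was tested on simulated data, in which 200 genes were changed by 1.5, 2 or 4-fold. The changed genes were drawn from those above a low level in the control, JQ1 and panobinostat groups. Each gene was simulated with the same dispersion in all groups. The shares below therefore do not cover the wider spread between the real duplicates of sanguinarine with panobinostat. For sanguinarine against control, 55.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold were called, and 3.6% of the calls were false. For sanguinarine with JQ1 against JQ1 the shares were 62.7%, 91% and 100%, with 4.5% false calls. For sanguinarine with panobinostat against panobinostat they were 68.7%, 95.5% and 100%, with 5.9% false calls. Interactions were called less often at the smaller folds, with 29.9%, 76.1% and 100% recovered for JQ1 and 28.4%, 77.6% and 100% for panobinostat, and false calls of 2.8% and 3.2%. A simulated list of 25 raised genes passed camera, and 0 of the other lists did. Simulated genes were independent of each other, so this gives no measure of false list calls where genes are correlated.

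Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a fit of only the groups compared, a replicate block where titles carried replicate numbers, and leaving out each replicate in turn. Fits of only the table concerned and of only genes that overlap no other gene, and a split of the control libraries between the alkaloids of a pair, were added after seeing the data. The pseudocount alternative was not run, because the files hold counts. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The RPKM columns were not used here beyond the check of their unit. With 2 libraries per group, no permutation of group labels could reach a p under 0.05, so only models that pool the spread over genes and groups were used.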

Results

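RNA was sequenced from NCI-H1688 cells, a human small cell lung cancer line, after 24 h with sanguinarine chloride (1 µM, a benzophenanthridine alkaloid), cepharanthine (3 µM, a bisbenzylisoquinoline alkaloid) or evodiamine (3 µM, an indole alkaloid), each alone. Further cells received the BET inhibitor JQ1 (28 µM) or the histone deacetylase inhibitor panobinostat (60 nM), alone or with sanguinarine. Each group held 2 biological duplicates, including the control. Counted reads per library were 43289277 and 53877601 in the control, 50290432 and 52794097 with sanguinarine, 51511983 and 56290153 with cepharanthine, and 55695761 and 54656344 with evodiamine. They were 42607877 and 41363658 with JQ1, 39996881 and 41831974 with panobinostat, 55323447 and 64060919 with sanguinarine and JQ1, and 54301377 and 50448944 with sanguinarine and panobinostat. The control and the single alkaloids stood in the first deposited table, and the other groups in the second.

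The first principal component of log2 CPM (63.7% of the variance) parted the groups with JQ1 or panobinostat from the control and the single alkaloids, and the second (17.3%) parted JQ1 from panobinostat. Over all 44591 gene rows, log2(CPM + 1) correlated at 0.995 to 0.999 in the 8 replicate pairs, at 0.964 to 0.997 between groups of the same table and at 0.934 to 0.956 between tables, and genes are not independent replicates. Over genes with at least 20 reads in a pair, replicates correlated at 0.9892 for sanguinarine with panobinostat and at 0.9961 to 0.9979 in the other groups. Duplicates of sanguinarine with panobinostat differed most, with a chi-square per degree of freedom of 83.81 against 5.63 in the control. The tables also differed in the classes of RNA counted. Different counting over overlapping genes may explain part of this. Of the 164 genes with no counts in the first table, 109 were antisense, and the 164 took 0.39% to 0.47% of second-table counts. A difference in the RNA itself cannot be told apart from one in counting here. Protein-coding genes took 97.86% to 98.26% of the counts in the first table and 94.77% to 96.21% in the second, and antisense and long intergenic RNAs took 0.73% to 0.9% and 2.4% to 3.26%. MALAT1, a nuclear non-coding RNA that overlaps another gene by position and was chosen after its values were seen, stood at 48.8 to 115.9 CPM in the first table and 2062.9 to 5961.9 CPM in the second. Because the first component also follows the tables, comparisons within a table carry the most weight below.

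**Figure D1:**
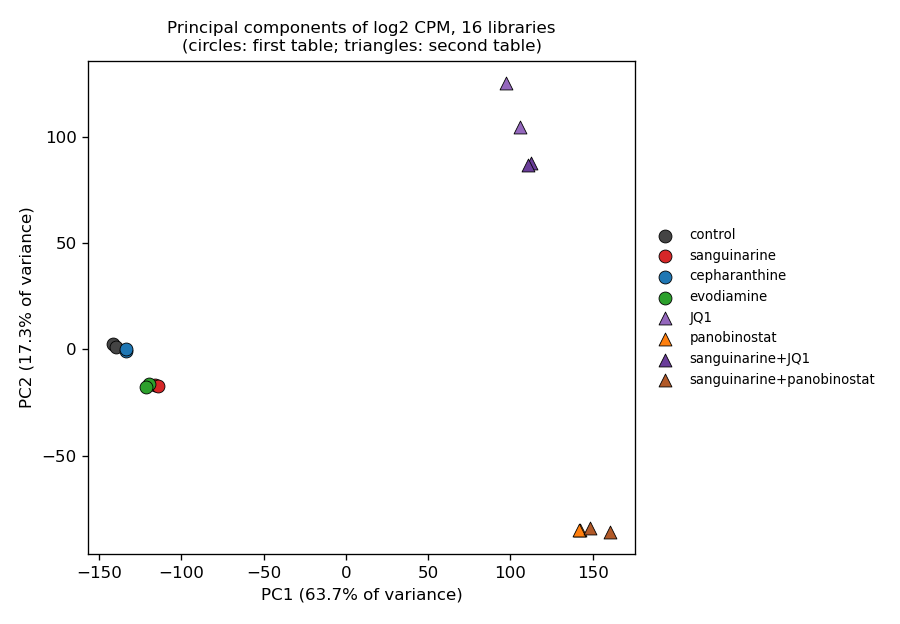
Principal components 1 (63.7%) and 2 (17.3%) of log2 CPM, with a point per library, circles for the first table and triangles for the second. First-table libraries lie at negative values of component 1 and second-table libraries at positive values, where JQ1 groups lie at positive and panobinostat groups at negative values of component 2.

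The first question was what sanguinarine alone does to these cells. HMOX1 (NCBI gene 3162), which encodes the heme-degrading enzyme heme oxygenase 1, rose from 1.57 ± 0.19 CPM in the control to 212 ± 24 CPM (SD, n = 2), a log2 change of 6.93 (95% interval 6.64 to 7.22, adjusted p = 9.47e-18, edgeR). AKR1C1 (NCBI gene 1645), an aldo-keto reductase, rose by 5.60 ± 0.20 on the log2 scale, and the ferritin heavy chain FTH1 rose by 3.06 ± 0.09. The amino acid synthesis gene ASNS rose by 2.59 ± 0.13, while all 13 mRNAs encoded by mitochondrial DNA fell, among them COX1 of cytochrome oxidase by 2.26 ± 0.13. In all, 2604 genes rose and 2291 fell, and 1134 rose and 260 fell by more than 2-fold. Which direction held more calls depended on the scaling, with 53.2% higher here and 48.9% with DESeq2 size factors.

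Among 24 targets of NRF2, the regulator of antioxidant genes, 21 rose with sanguinarine and 3 did not pass (22 rose adjusted over the list alone, median log2 change 1.17, camera adjusted p = 1.1e-23). AKR1C2 rose by 4.05 ± 0.18 and NQO1, a quinone reductase, by 1.17 ± 0.10. Reads of AKR1C1 and AKR1C2, which are close paralogs, and of FTH1, which has processed pseudogenes, may be shared in part with their relatives. The integrated stress response genes under ATF4 moved the same way, with 17 of 23 higher, 2 lower and 4 not passing (17 higher and 2 lower adjusted over the list alone, adjusted p = 2.86e-14). Their largest rises included NUPR1, a stress-induced chromatin protein, at 2.78 ± 0.18, the serine synthesis enzyme PHGDH at 1.52 ± 0.09, PCK2 at 1.55 ± 0.10 and the transcription factor DDIT3 at 1.06 ± 0.14.

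Other lists moved upward as well. Of 24 p53 targets, 12 rose and 12 did not pass (14 rose adjusted over the list alone, adjusted p = 9.21e-08), with GDF15, a secreted stress cytokine, at 2.38 ± 0.17, TP53INP1 at 1.87 ± 0.13 and the cell cycle inhibitor CDKN1A at 1.19 ± 0.10. Lysosome and autophagy genes rose in 18 of 31 cases and none fell, with 13 not passing (19 adjusted over the list alone, adjusted p = 9.73e-10), including the autophagy receptor SQSTM1 at 1.64 ± 0.10. NF-kB targets rose in 12 of 19 cases, 2 fell and 5 did not pass (12 and 2 adjusted over the list alone, adjusted p = 5.78e-06), with the cytokine gene IL6 at 2.44 ± 0.17 and the chemokine gene CCL20 at 1.49 ± 0.17. Aryl hydrocarbon receptor targets rose in 5 of 8 cases, 1 fell and 2 did not pass (5 and 1 adjusted over the list alone, adjusted p = 0.00713), and the cytochrome gene CYP1B1 rose by 1.06 ± 0.19.

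Proliferation genes fell with sanguinarine. Of 30 G1/S and replication genes, 28 fell and 2 did not pass (30 fell adjusted over the list alone, median −0.70, adjusted p = 1.37e-27), including the replication factor GINS2 at −1.16 ± 0.11 and the helicase subunit MCM3 at −0.86 ± 0.09. Of 30 G2/M genes, 28 fell and 2 did not pass (29 fell adjusted over the list alone, adjusted p = 8.58e-26), with the proliferation marker MKI67 at −1.11 ± 0.12 and the mitotic kinase PLK1 at −0.99 ± 0.09. Ribosome biogenesis genes of the MYC target list fell in 22 of 29 cases and 7 did not pass (22 adjusted over the list alone, adjusted p = 7.99e-17), although MYC itself had a value of −0.09 ± 0.09 (adjusted p = 0.489). NCL, which encodes nucleolin, fell by 0.72 ± 0.08 on the log2 scale. The mitochondrially encoded mRNAs had a median of −2.01 (13 fell adjusted over the list alone, adjusted p = 1.37e-27), and their share of all counts dropped from 3.78% and 3.85% in the control libraries to 0.9% and 0.98%.

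Heat shock genes fell in 13 of 20 cases, 2 rose and 5 did not pass (14 fell and 2 rose adjusted over the list alone, adjusted p = 8.85e-07), and this list did not pass with an estimated correlation (adjusted p = 0.0914). HSPA8, a constitutive chaperone, fell by 1.06 ± 0.09. Of 17 lists that passed, 10 also passed with an estimated correlation, and these include every list above apart from the heat shock genes. Outside the lists, the keratin gene KRT4 (NCBI gene 3851) fell by 3.60 ± 0.32 and the angiopoietin-like gene ANGPTL4 rose by 3.75 ± 0.16. The total of 4895 changed genes was 2779 without control 1, 2665 without control 2, 2815 without sanguinarine 1 and 2679 without sanguinarine 2, but 8741 in a fit of only the groups compared and 7867 in a fit of only that table.

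**Figure D2:**
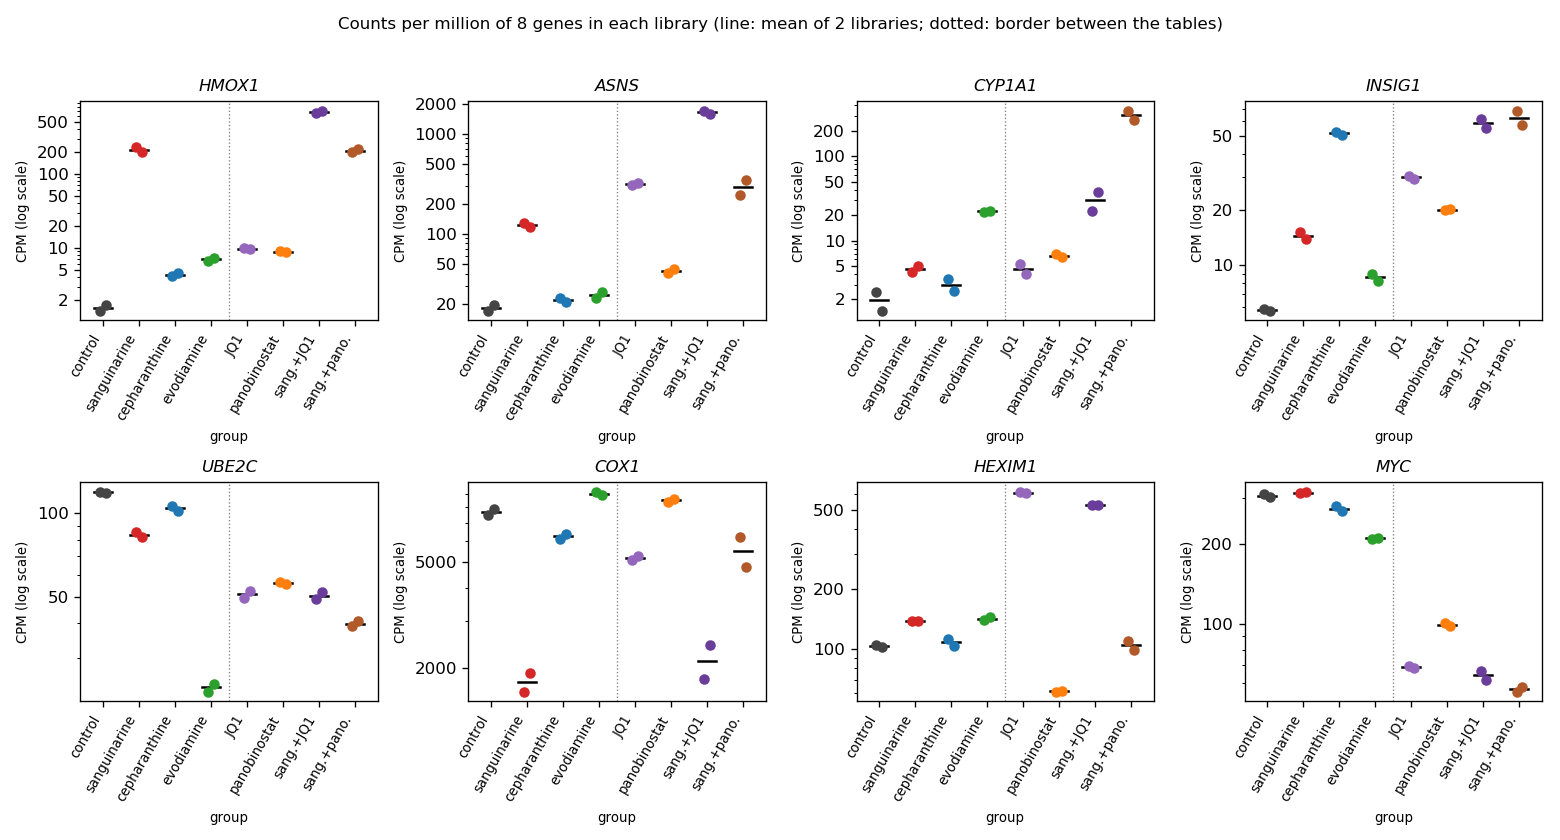
CPM per library on a log axis for HMOX1, ASNS, CYP1A1, INSIG1, UBE2C, COX1, HEXIM1 and MYC, with a point per library, a line at the mean of 2 and a dotted line between the tables. HMOX1 stood at 212 ± 24 CPM with sanguinarine and 689 ± 21 with sanguinarine and JQ1, against 1.57 ± 0.19 CPM in the control.

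Cepharanthine was compared with the control in the same way. INSIG1 (NCBI gene 3638), a sterol-sensing regulator, rose from 5.77 ± 0.074 to 51.4 ± 1 CPM, a log2 change of 3.13 ± 0.13 (adjusted p = 7.19e-12, edgeR), and the sterol exporters ABCG1 and ABCA1 fell by 4.89 ± 0.25 and 4.55 ± 0.28, the latter by 5.27 without cepharanthine 1. In all, 579 genes rose and 214 fell, and 199 rose and 69 fell by more than 2-fold.

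Of 26 cholesterol synthesis genes, 24 rose with cepharanthine and 2 did not pass (25 rose adjusted over the list alone, median 1.40, camera adjusted p = 1.19e-72). HMGCS1, an early enzyme of the pathway, rose by 2.34 ± 0.11, MSMO1 by 2.32 ± 0.15 and IDI1 by 2.06 ± 0.11. The fatty acid desaturase SCD rose by 2.85 ± 0.12, while MYLIP, which encodes a ubiquitin ligase, fell by 2.81 ± 0.22. Lysosome and autophagy genes rose in 11 of 31 cases and 20 did not pass (15 adjusted over the list alone, adjusted p = 1.02e-14), among them WIPI1 at 1.18 ± 0.13 and the cholesterol transporter NPC1 at 0.91 ± 0.11. MYC targets fell in 5 of 29 cases and 24 did not pass (16 fell adjusted over the list alone, adjusted p = 2.55e-15), and MYC had a value of −0.19 ± 0.09 (adjusted p = 0.309).

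Hypoxia and glycolysis genes rose in 12 of 23 cases with cepharanthine and 11 did not pass (13 rose adjusted over the list alone, adjusted p = 1.78e-12, adjusted p = 0.176 with an estimated correlation), with the stress gene NDRG1 at 2.19 ± 0.23 and the glucose transporter SLC2A3 at 1.64 ± 0.18. NRF2 targets rose in 6 of 24 cases and 18 did not pass (7 adjusted over the list alone, adjusted p = 0.000775, adjusted p = 0.176 with an estimated correlation), with HMOX1 at 1.43 ± 0.14 and the ferritin light chain FTL at 0.78 ± 0.11. Of 15 lists that passed, 3 also passed with an estimated correlation, namely the sterol, lysosome and MYC target lists. The total of 793 changed genes was 352 without control 1, 365 without control 2, 374 without cepharanthine 1 and 404 without cepharanthine 2, but 2640 in a fit of only the groups compared, 3175 in a fit of only that table and 1243 with the DESeq2 Wald test.

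Evodiamine, the third alkaloid, was set against the same control. UBE2C (NCBI gene 11065), a ubiquitin-conjugating enzyme of mitotic exit, fell from 119 ± 0.22 to 23.5 ± 1 CPM, a log2 change of −2.39 ± 0.09 (adjusted p = 3.91e-12, edgeR). TOP2A, the replication and mitosis topoisomerase, fell by 2.25 ± 0.12 and the tubulin gene TUBB (NCBI gene 203068) by 1.56 ± 0.09. CYP1A1 (NCBI gene 1543), the classic target of the aryl hydrocarbon receptor, rose from 1.98 ± 0.7 to 22.1 ± 0.77 CPM, a log2 change of 3.44 ± 0.25 (adjusted p = 1.68e-08). In all, 1181 genes rose and 1365 fell, and 581 rose and 251 fell by more than 2-fold.

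Of 24 p53 targets, 21 rose with evodiamine and 3 did not pass (23 rose adjusted over the list alone, median 0.64, camera adjusted p = 1.1e-27), with TP53INP1 at 1.89 ± 0.13, the p53 ligase MDM2 at 1.19 ± 0.10, BTG2 at 1.15 ± 0.09 and CDKN1A at 1.11 ± 0.10. G1/S genes fell in 26 of 30 cases and 4 did not pass (30 fell adjusted over the list alone, median −0.65, adjusted p = 3.24e-35), including the uracil glycosylase UNG at −1.28 ± 0.10 and E2F1 at −1.01 ± 0.13. The G2/M list did not pass (7 higher and 9 lower of 30, adjusted p = 0.0777), and its median of 0.01 and mean of −0.29 had opposite signs. Its members CDK1 and UBE2C fell by 2.21 ± 0.16 and 2.39 ± 0.09. Tubulins fell in 4 of 15 cases and 11 did not pass (4 adjusted over the list alone, adjusted p = 0.00386, adjusted p = 0.509 with an estimated correlation). Tubulin genes are similar in sequence, and reads may be shared between them.

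NF-kB targets rose in 12 of 19 cases with evodiamine and 7 did not pass (12 adjusted over the list alone, adjusted p = 3.69e-14), with TRAF1 at 2.48 ± 0.19, IL6 at 2.08 ± 0.17 and CXCL8, which encodes interleukin 8, at 1.72 ± 0.17. Interferon-stimulated genes rose in 11 of 22 cases, 1 fell and 10 did not pass (16 rose and 2 fell adjusted over the list alone, adjusted p = 8.49e-06), including IFI6 at 1.08 ± 0.20 and MX1 at 0.61 ± 0.11. Aryl hydrocarbon receptor targets rose in 3 of 8 cases and 5 did not pass (4 adjusted over the list alone, adjusted p = 0.000854), with CYP1B1 at 2.51 ± 0.19. NRF2 targets rose in 11 of 24 cases and 13 did not pass (12 rose and 1 fell adjusted over the list alone, adjusted p = 0.000479, adjusted p = 0.173 with an estimated correlation). The transcription factor ATF3 rose by 2.48 ± 0.15 and MYC fell by 0.59 ± 0.09. Of 10 lists that passed, 6 also passed with an estimated correlation. The total of 2546 changed genes was 1087 without control 1, 1144 without control 2, 1255 without evodiamine 1 and 1076 without evodiamine 2, but 6018 in a fit of only the groups compared and 5585 in a fit of only that table.

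The alkaloids were next compared with each other, at doses that differ, since sanguinarine was given at 1 µM and the other two at 3 µM. HMOX1 was higher with sanguinarine than with cepharanthine by 5.50 (95% interval 5.24 to 5.76) and than with evodiamine by 4.84 (4.59 to 5.09) on the log2 scale. ASNS was higher by 2.36 (2.09 to 2.64) and 2.23 (1.96 to 2.50). The sterol exporter ABCG1 was higher with sanguinarine than with cepharanthine by 4.54 (4.01 to 5.08). UBE2C was higher with sanguinarine than with evodiamine by 1.75 (1.56 to 1.94), and CYP1A1 was lower, with a difference of −2.34 (−2.81 to −1.87). The difference in CDKN1A between sanguinarine and evodiamine was 0.08 with an interval of −0.12 to 0.28 (adjusted p = 0.608), and that in CYP1A1 between sanguinarine and cepharanthine was 0.52 with an interval of 0 to 1.04 (adjusted p = 0.18).

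Against cepharanthine, sanguinarine gave higher NRF2 targets in 20 of 24 cases with 4 not passing (23 adjusted over the list alone, adjusted p = 3.77e-28), and AKR1C1 differed by 4.16 ± 0.18. The cholesterol list was lower in 23 of 26 cases with 3 not passing (23 adjusted over the list alone, adjusted p = 1.76e-37), and HMGCS1 differed by −2.15 ± 0.11. Mitochondrial mRNAs were lower in 13 of 13 cases, with 13 adjusted over the list alone (adjusted p = 9.72e-30). Against evodiamine, NRF2 targets were higher in 17 of 24 cases with 7 not passing (18 adjusted over the list alone, adjusted p = 4.25e-18), and ALDH1L2, a mitochondrial folate enzyme, differed by 4.28 ± 0.19. The p53 list was higher in 2 cases, lower in 13 and not passing in 9 (2 and 13 adjusted over the list alone, adjusted p = 1.96e-06), with MDM2 differing by −0.54 ± 0.10. Mitochondrial mRNAs were lower in 13 of 13 cases here too, with 13 adjusted over the list alone (adjusted p = 2.76e-28).

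Between cepharanthine and evodiamine, p53 targets were lower with cepharanthine in 22 of 24 cases and 2 did not pass (22 adjusted over the list alone, camera adjusted p = 1.46e-26), with BTG2 differing by −1.56 ± 0.09. G1/S genes were higher in 21 of 30 cases and 9 did not pass (24 adjusted over the list alone, adjusted p = 5.28e-23), with E2F1 differing by 1.04 ± 0.13, and NF-kB targets were higher in 2 and lower in 13 of 19 cases with 4 not passing (3 and 13 adjusted over the list alone, adjusted p = 1.42e-07). HMOX1 differed by −0.66 ± 0.12. All lists named in these contrasts also passed with an estimated correlation.

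Changed genes numbered 3267 between sanguinarine and cepharanthine (1505 without sanguinarine 1, 1361 without sanguinarine 2, 1932 without cepharanthine 1 and 1312 without cepharanthine 2, but 5998 from only the groups compared and 6563 from only that table). They numbered 4563 between sanguinarine and evodiamine (2627 without sanguinarine 1, 2252 without sanguinarine 2, 2684 without evodiamine 1 and 2337 without evodiamine 2, but 8225 and 7691 in those fits). Cepharanthine and evodiamine differed in 3131 genes (1611 without cepharanthine 1, 1603 without cepharanthine 2, 1656 without evodiamine 1 and 1467 without evodiamine 2, but 5193 and 6233 in those fits).

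Genes called with more than 1 alkaloid were counted to ask how far the responses overlap. With all 3 alkaloids, 185 genes rose and 38 fell. Sanguinarine and cepharanthine both raised 408 genes and both lowered 120, where independent lists would share 67.7 and 22, and 32 genes moved in opposite directions. Sanguinarine and evodiamine both raised 641 and lowered 544 (138 and 140 for independent lists), with 96 opposite, and cepharanthine and evodiamine both raised 205 and lowered 49 (30.7 and 13.1), with 59 opposite. In 20 simulations of groups equal to the control, at most 3 genes were called and at most 1 was shared, so these give no measure of the overlap of lists as long as the ones observed. Correlations of fold changes across genes were 0.509, 0.604 and 0.455 in the same order, against 0.53, 0.539 and 0.531 simulated from the shared controls alone. The covariances were 0.5117, 0.7165 and 0.4604, against simulated values of 0.2203, 0.2215 and 0.22. The controls were then split, a choice made after seeing the data, with the first alkaloid of a pair set against control 1 and the second against control 2. The covariances were then 0.2341, 0.5048 and 0.211, and with the controls exchanged 0.2337, 0.4754 and 0.1819, against simulated values of 0.0216 to 0.0249. Under the first split, with fewer genes called, the pairs both raised 160, 230 and 61 genes (17.3, 29.7 and 5.4 for independent lists) and both lowered 39, 214 and 11 (4.53, 34.7 and 2.98). The numbers for independent lists take every tested gene as equally likely to be called, so they may be too low. The control is labelled untreated, whereas the design describes DMSO. A vehicle effect common to the alkaloids would remain after the split and was not tested.

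JQ1 and panobinostat were compared with the control to ask what the partner drugs do alone, although here the table and the drug cannot be told apart. With JQ1, HEXIM1 (NCBI gene 10614), a known marker gene of BET inhibition that overlaps another gene by position, rose from 103 ± 2.6 to 612 ± 5.3 CPM, a log2 change of 2.55 ± 0.10 (adjusted p = 1.23e-14, edgeR). The transcription factor gene MYC (NCBI gene 4609) fell by 2.17 ± 0.09, and the cytokine genes IL1B and IL1A fell by 8.67 ± 0.22 and 6.07 ± 0.21. SERPINI1, a serine protease inhibitor, rose by 7.63 ± 0.32 and ASNS by 4.08 ± 0.14. In all, 7059 genes rose and 6496 fell.

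Of 12 BET inhibitor response genes, 12 rose with JQ1 (12 adjusted over the list alone, camera adjusted p = 6.79e-09). MYC targets rose in 1 and fell in 27 of 29 cases with 1 not passing (1 and 27 adjusted over the list alone, adjusted p = 5.92e-16), including NOLC1 at −2.02 ± 0.08. G1/S genes fell in 29 of 30 cases and 1 did not pass (30 fell adjusted over the list alone, adjusted p = 2.05e-17), with MCM5 at −3.80 ± 0.12 and GINS2 at −3.76 ± 0.12. Lysosome genes rose in 25, fell in 3 and did not pass in 3 of 31 cases (25 and 4 adjusted over the list alone, adjusted p = 7.89e-08), with the sialidase NEU1 at 2.84 ± 0.14. Polyadenylated histone genes, some of which are also in the BET list, rose in 13 of 13 cases (13 adjusted over the list alone, adjusted p = 8.43e-09, adjusted p = 0.178 with an estimated correlation), with HIST1H2AC at 4.46 ± 0.19, and these genes resemble each other in sequence. Beside these lists, MALAT1, which overlaps another gene, was higher in the JQ1 libraries than in the control by 5.50 ± 0.15. The different counting over overlapping genes may add to that value. RNR2, a mitochondrial ribosomal RNA and the top gene of both JQ1 libraries, was higher by 2.37 ± 0.11. Of 11 lists that passed, 5 also passed with an estimated correlation.

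Panobinostat was likewise compared with the control in the other table. SYT11, a synaptotagmin, rose by 8.60 ± 0.25 (adjusted p = 3.03e-16, edgeR), and the adhesion gene NCAM1 (NCBI gene 4684), which overlaps another gene, rose from 0.0532 ± 0.023 to 41.3 ± 3.7 CPM. FOSL1, an AP-1 subunit, fell by 6.13 ± 0.15, the follistatin gene FST fell by 4.87 ± 0.14 and MYC fell by 1.80 ± 0.09. The carboxypeptidase gene CPA4 rose by 6.30 ± 0.16, and ATCAY, with 0 counts in the control, was at least 360-fold higher. In all, 7957 genes rose and 6754 fell.

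Of 18 neuroendocrine genes, 13 rose with panobinostat, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone, adjusted p = 0.00656, adjusted p = 0.307 with an estimated correlation). The granin gene CHGB rose by 2.94 ± 0.27 and the neuronal enolase ENO2 by 1.49 ± 0.14. MYC targets rose in 1 and fell in 27 of 29 cases with 1 not passing (1 and 27 adjusted over the list alone, adjusted p = 3.19e-15), and G1/S genes fell in 29 of 30 with 1 not passing (29 adjusted over the list alone, adjusted p = 6.66e-16), UNG by 3.25 ± 0.11. The p53 list moved down, with 5 higher, 14 lower and 5 not passing of 24 (5 and 15 adjusted over the list alone, adjusted p = 0.0324, adjusted p = 0.307 with an estimated correlation), including the nuclease AEN at −2.50 ± 0.11. Drug target and acetyltransferase genes rose in 4, fell in 15 and did not pass in 5 of 24 cases (4 and 15 adjusted over the list alone, adjusted p = 0.00573, adjusted p = 0.307 with an estimated correlation), with the acetyltransferase CREBBP at −2.57 ± 0.13. Beside these lists, MALAT1 was higher in the panobinostat libraries by 6.51 ± 0.16 and RNR2, their top gene, by 1.53 ± 0.10. The different counting over overlapping genes may add to the MALAT1 value here too. Of 11 lists that passed, 3 also passed with an estimated correlation.

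A direct comparison of JQ1 with panobinostat stays within the second table. HEXIM1 was higher with JQ1 by 3.49 ± 0.10 (adjusted p = 3.09e-15, edgeR) and the bromodomain gene BRD2 by 3.09 ± 0.10, whereas NCAM1 and CHGB were lower, with differences of −6.54 ± 0.29 and −2.45 ± 0.26. Of 24 p53 targets, 23 were higher with JQ1 and 1 did not pass (23 adjusted over the list alone, adjusted p = 3.35e-11), including TP53INP1 at 2.38 ± 0.12 and CDKN1A at 1.25 ± 0.10. Neuroendocrine genes were lower in 12 of 18 cases and 6 did not pass (12 adjusted over the list alone, adjusted p = 0.000468, adjusted p = 0.127 with an estimated correlation). Histone genes were higher in 11 of 13 cases and 2 did not pass (11 adjusted over the list alone, adjusted p = 6.98e-07, adjusted p = 0.243 with an estimated correlation). MYC differed by −0.37 ± 0.09, and 5968 genes were higher and 6475 lower with JQ1.

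What sanguinarine changes in cells that also receive JQ1 was asked within the second table. HMOX1 was higher with the combination than with JQ1 alone by 6.06 ± 0.12 (adjusted p = 1.55e-17, edgeR), at 689 ± 21 against 9.73 ± 0.18 CPM. The chemokine gene CCL20 was higher by 4.80 ± 0.18, the collagenase gene MMP1 (NCBI gene 4312) by 6.31 ± 0.29 and the cornified envelope gene SPRR2A by 7.42 ± 0.35, and reads of SPRR2A may be shared with its paralogs. KRT14, a basal keratin, and DKK1, a secreted Wnt antagonist, were lower, with differences of −3.13 ± 0.17 and −2.49 ± 0.11. In all, 3608 genes were higher and 3073 lower, and 1624 were higher and 542 lower by more than 2-fold.

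Of 23 ATF4 response genes, 20 were higher, 1 lower and 2 did not pass (20 and 1 adjusted over the list alone, median 1.36, camera adjusted p = 8.02e-21), with the glutathione-degrading enzyme CHAC1 at 2.68 ± 0.14, ASNS at 2.29 ± 0.13 and DDIT3 at 2.23 ± 0.13. NRF2 targets were higher in 20 of 24 cases and 4 did not pass (21 adjusted over the list alone, median 1.14, adjusted p = 8.4e-18), with AKR1C1 at 3.74 ± 0.18 and the sulfiredoxin gene SRXN1 at 2.64 ± 0.09. Mitochondrial mRNAs were lower in 13 of 13 cases (13 adjusted over the list alone, median −1.54, adjusted p = 8.4e-18, adjusted p = 0.0952 with an estimated correlation), with ND4 at −2.11 ± 0.15. NF-kB targets were higher in 11, lower in 1 and not passing in 7 of 19 cases (11 and 1 adjusted over the list alone, adjusted p = 4.98e-06, adjusted p = 0.0926 with an estimated correlation), with IL1B at 3.77 ± 0.26. BET inhibitor response genes were lower in 9, higher in 2 and not passing in 1 of 12 cases (9 and 2 adjusted over the list alone, adjusted p = 0.000213, adjusted p = 0.0926 with an estimated correlation), including HIST1H2BK at −2.16 ± 0.15.

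Epithelial markers were higher in 3, lower in 7 and not passing in 5 of 15 cases (3 and 10 adjusted over the list alone, adjusted p = 0.000119, adjusted p = 0.0906 with an estimated correlation), with the keratin KRT8 at −1.37 ± 0.09. Tubulins were higher in 8 of 15 cases and 7 did not pass (8 adjusted over the list alone, adjusted p = 0.00348, adjusted p = 0.405 with an estimated correlation), TUBA1A by 1.85 ± 0.16. Blood cell markers, a list for another cell type, were higher in 4 of 6 cases and 2 did not pass (4 adjusted over the list alone, adjusted p = 0.0182, adjusted p = 0.269 with an estimated correlation). CD68, a macrophage marker, was higher by 1.60 ± 0.15, at 32.7 ± 2.1 against 10.2 ± 0.94 CPM, and the hemoglobin gene HBA1 by 3.32 ± 0.57, at 2.29 ± 0.14 CPM. Fibroblast markers passed in none of the 17 comparisons. MYC had a value of −0.18 ± 0.09 (adjusted p = 0.12) and CDKN1A of −0.13 ± 0.10 (adjusted p = 0.338). Of 19 lists that passed, 2 also passed with an estimated correlation, namely the ATF4 and NRF2 lists.

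The same was asked with panobinostat as the partner. CYP1A1 was higher with the combination than with panobinostat alone by 5.42 ± 0.24 (adjusted p = 1.63e-11, edgeR), at 306 ± 51 against 6.62 ± 0.43 CPM, and CYP1B1 was higher by 4.49 ± 0.21. HMOX1 was higher by 4.43 ± 0.12, ANGPTL4 by 3.67 ± 0.16 and the neuronal immediate early gene ARC by 4.36 ± 0.31. The interferon-stimulated gene IFIT1, KRT14 and MYC were lower, with differences of −2.10 ± 0.13, −1.99 ± 0.16 and −0.92 ± 0.09. In all, 2561 genes were higher and 2546 lower, and 773 were higher and 227 lower by more than 2-fold.

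Aryl hydrocarbon receptor targets were higher in 5 of 8 cases and 3 did not pass (6 adjusted over the list alone, camera adjusted p = 2.69e-06). This was the only list of the 11 that passed here to pass also with an estimated correlation. ATF4 response genes were higher in 18, lower in 1 and not passing in 4 of 23 cases (19 and 2 adjusted over the list alone, median 0.87, adjusted p = 2.89e-12, adjusted p = 0.0584 with an estimated correlation), with ASNS at 2.68 ± 0.13, CHAC1 at 2.08 ± 0.14 and DDIT3 at 2.03 ± 0.14. Mitochondrial mRNAs were lower in 12 of 13 cases and 1 did not pass (13 adjusted over the list alone, median −0.91, adjusted p = 2.45e-12, adjusted p = 0.248 with an estimated correlation), with COX3 at −1.50 ± 0.15. G2/M genes were higher in 1, lower in 22 and not passing in 7 of 30 cases (2 and 25 adjusted over the list alone, adjusted p = 2.86e-10, adjusted p = 0.264 with an estimated correlation), with TOP2A at −0.78 ± 0.12. NRF2 targets were higher in 9, lower in 2 and not passing in 13 of 24 cases (12 and 2 adjusted over the list alone, adjusted p = 0.000529, adjusted p = 0.248 with an estimated correlation), NQO1 by 1.17 ± 0.10. The total of 5107 changed genes was 2068 without panobinostat 2, 7836 without sanguinarine and panobinostat 2, 1772 in a fit of only the groups compared and 3135 in a fit of only that table.

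**Figure D3:**
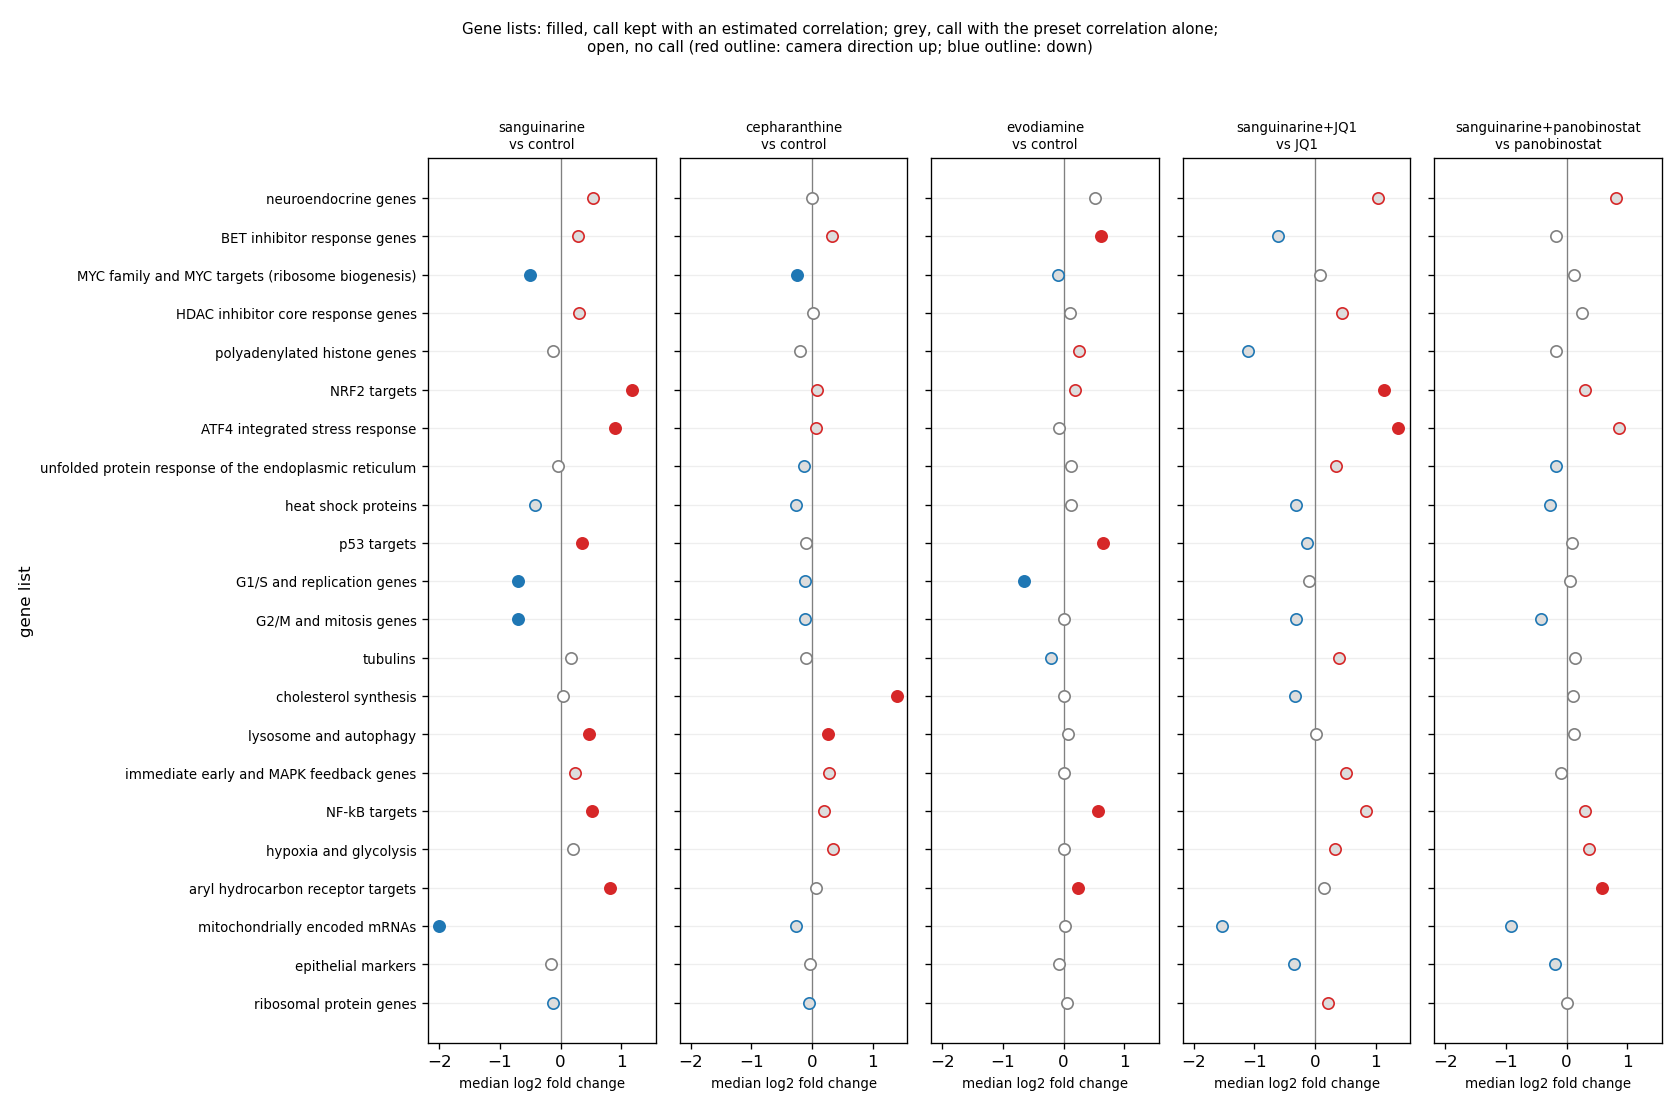
Median log2 fold change of each gene list in 5 comparisons, with a panel per comparison, for lists that passed camera in at least 2 of them. Filled points passed with an estimated correlation, grey points only with the preset correlation and open points not at all, and red and blue outlines give the direction as up or down. The cholesterol list lies at 1.40 with cepharanthine, and mitochondrial mRNAs lie at −2.01 with sanguinarine.

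Whether the change with sanguinarine differed in cells with a partner drug was tested by the interaction. An additive difference between the tables on the log2 scale cancels in it. An effect of sanguinarine that itself differed between the tables would not cancel, and cannot be told apart from an effect of the partner drug. Both interactions share the control and sanguinarine libraries, so they are not separate evidence. Additivity is meant on the log2 scale, where folds multiply. A downward departure is thus a smaller rise, a larger fall or a fall in place of a rise on that scale. It need not be a lower level or a smaller rise in CPM. An upward departure is likewise a larger rise, a smaller fall or a rise in place of a fall. A difference in counting over overlapping genes need not cancel, and of the genes named for the interactions MMP1, CDKN1A, GDF15, RRP12, HIST1H2BK, GABARAPL1 and FTH1 overlap another gene. With JQ1, 2189 genes departed upward and 1836 downward, 4025 in all against 6427 in a fit of only the groups compared. MMP1 departed by 5.94 ± 0.36 (adjusted p = 2.57e-09, edgeR), at 31.2 ± 11 CPM in the combination against 0.37 ± 0.058 with JQ1, 10.1 with sanguinarine and 7.09 in the control. FOSL1 departed by 2.40 ± 0.16 and E2F1 by 1.70 ± 0.19. TP53INP1 (NCBI gene 94241) departed by −2.84 ± 0.17, since it stood at 7.81 ± 1.1 CPM in the control, 31.5 ± 0.74 with sanguinarine, 128 ± 0.78 with JQ1 and 68.8 ± 1.1 with both. CDKN1A departed by −1.32 ± 0.14, GDF15 by −2.36 ± 0.22 and HMOX1 by −0.87 ± 0.17. In CPM, HMOX1 was nonetheless higher with both drugs than with sanguinarine or JQ1 alone.

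Of 24 p53 targets, 1 departed upward from additivity with JQ1, 14 downward and 9 did not pass (1 and 15 adjusted over the list alone, median −0.66, camera adjusted p = 7.22e-10). G1/S genes departed upward in 19 of 30 cases and 11 did not pass (22 adjusted over the list alone, adjusted p = 2.03e-12), with MCM3 at 1.03 ± 0.13, and MYC targets in 15 of 29 with 14 not passing (17 adjusted over the list alone, adjusted p = 2.73e-11), with RRP12 at 0.95 ± 0.13. BET inhibitor response genes departed downward in 6 of 12 cases and 6 did not pass (7 adjusted over the list alone, adjusted p = 5.91e-06), with HIST1H2BK at −2.05 ± 0.21. Lysosome genes departed upward in 2, downward in 12 and did not pass in 17 of 31 cases (3 and 17 adjusted over the list alone, adjusted p = 7.07e-06), with GABARAPL1 at −1.45 ± 0.14, and cholesterol genes upward in 1 and downward in 10 of 26 with 15 not passing (1 and 10 adjusted over the list alone, adjusted p = 0.000108). These lists were the 6 of 15 that also passed with an estimated correlation.

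With panobinostat, 1760 genes departed upward and 1926 downward. The balance depended on the scaling, with 47.7% of calls upward here and 50.8% with DESeq2 size factors. CYP1A1 departed by 4.32 ± 0.36 (adjusted p = 1.92e-07, edgeR), CYP1B1 by 3.43 ± 0.28 and the matrix gene TNC by 3.19 ± 0.21. AKR1C1 departed by −5.07 ± 0.26 (adjusted p = 2.45e-10), at 2.08 ± 0.19 CPM in the control, 111 ± 16 with sanguinarine, 7.03 ± 1.1 with panobinostat and 11.1 ± 3.4 with both. FTH1 departed by −2.59 ± 0.13, HMOX1 by −2.50 ± 0.17 and MYC by −0.83 ± 0.12.

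NRF2 targets departed downward from additivity with panobinostat in 11 of 24 cases and 13 did not pass (17 adjusted over the list alone, median −0.72, adjusted p = 2.41e-13). G1/S genes departed upward in 22 of 30 cases and 8 did not pass (25 adjusted over the list alone, adjusted p = 2.59e-17), with E2F1 at 1.40 ± 0.19, and MYC targets upward in 18 and downward in 1 of 29 cases with 10 not passing (20 and 1 adjusted over the list alone, adjusted p = 6.22e-13), with NOLC1 at 1.11 ± 0.11. Mitochondrial mRNAs departed upward in 12 of 13 cases and 1 did not pass (13 adjusted over the list alone, median 1.08, adjusted p = 2.66e-13, adjusted p = 0.198 with an estimated correlation), with COX1 at 1.52 ± 0.18. Of 11 lists that passed, 3 also passed with an estimated correlation. The total of 3686 changed genes was 2167 without control 1, 2277 without sanguinarine 1, 2349 without sanguinarine 2, 2128 without panobinostat 2, 6345 without sanguinarine and panobinostat 2 and 2154 in a fit of only the groups compared.

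How far the response to sanguinarine carried over was also asked gene by gene. Across all tested genes, which are not independent replicates, the log2 changes of sanguinarine against control correlated with those of the combination against JQ1 at r = 0.21 (Spearman 0.221) and of the combination against panobinostat at r = 0.189 (Spearman 0.18). Over genes called with sanguinarine, r was 0.501 and 0.425, and 69% and 66.3% kept the same sign. Of 2604 genes that rose with sanguinarine, 1100 were also higher in the JQ1 combination and 207 lower, and 684 were higher and 220 lower in the panobinostat combination. Of 2291 that fell, 743 were also lower and 265 higher with JQ1, and 613 were lower and 199 higher with panobinostat. HMOX1 and ASNS rose in all 3 contrasts, and COX3 fell in all 3.

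**Figure D4:**
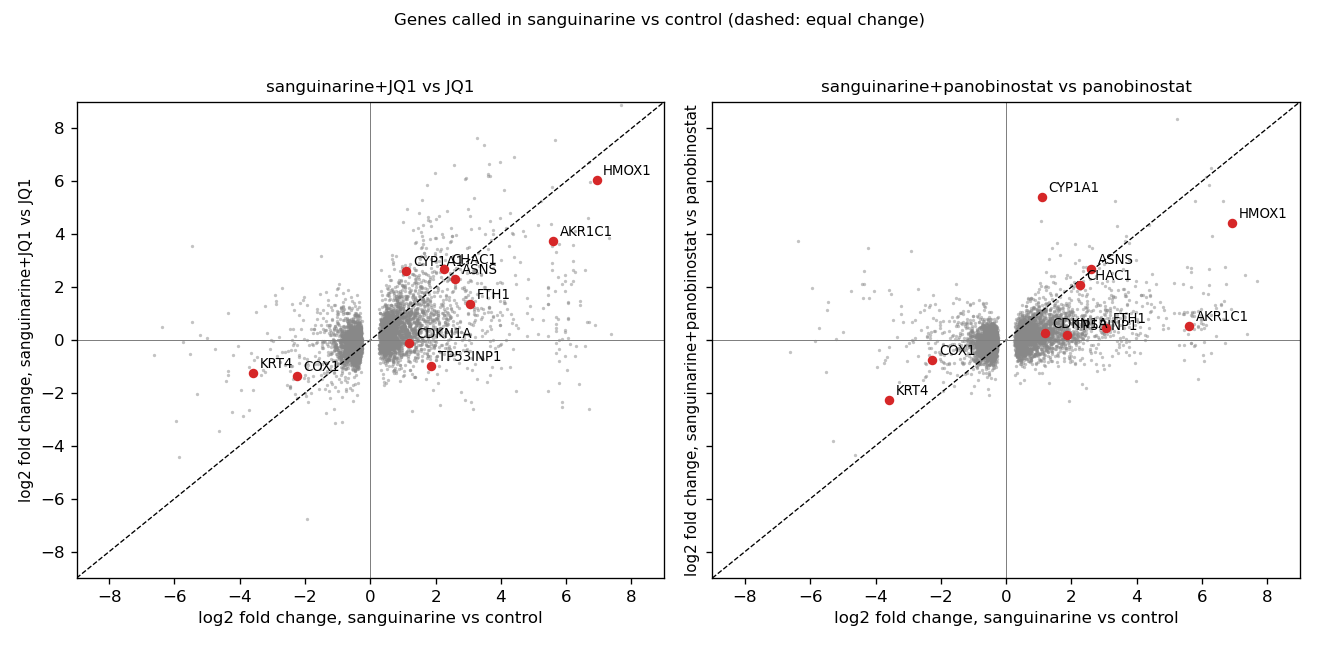
Log2 fold change of sanguinarine against control (x axis) and of each combination against its partner drug (y axis, a panel per partner), with a point per gene called with sanguinarine and a dashed line where both changes are equal. HMOX1 lies at 6.93 on the x axis, and at 6.06 with JQ1 and 4.43 with panobinostat on the y axis.

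The combinations were finally set against the control and against sanguinarine alone, where the table and the drug cannot be told apart. The classes of RNA counted also differed between the tables, as given above. With sanguinarine and JQ1 against control, HMOX1 rose by 8.66 ± 0.15 (adjusted p = 1.64e-19, edgeR), ASNS by 6.37 ± 0.15 and SRXN1 by 3.89 ± 0.10, and MYC fell by 2.35 ± 0.09. NRF2 targets rose in 23 of 24 cases and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 4.27e-11), BET inhibitor response genes rose in 12 of 12 (12 adjusted over the list alone, adjusted p = 5.29e-08), and G1/S genes fell in 30 of 30 (30 adjusted over the list alone, adjusted p = 4.83e-18). In all, 7463 genes rose and 6465 fell. Against sanguinarine alone, 6630 genes were higher and 6300 lower, with SERPINI1 at 6.31 ± 0.30, ASNS at 3.78 ± 0.14 and MYC at −2.26 ± 0.09.

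With sanguinarine and panobinostat against control, SYT11 rose by 9.22 ± 0.25 (adjusted p = 1.15e-16, edgeR), CYP1A1 by 6.99 ± 0.27 and HMOX1 by 6.73 ± 0.14, and MYC fell by 2.73 ± 0.09. Neuroendocrine genes rose in 16 of 18 cases and 2 did not pass (16 adjusted over the list alone, adjusted p = 0.000541, adjusted p = 0.176 with an estimated correlation), with CHGB at 3.08 ± 0.27. MYC targets rose in 1, fell in 26 and did not pass in 2 of 29 cases (2 and 26 adjusted over the list alone, camera adjusted p = 7.15e-14). In all, 8458 genes rose and 6858 fell. Blood cell markers rose in 5 of 6 cases and 1 did not pass (5 adjusted over the list alone, adjusted p = 0.0428, adjusted p = 0.374 with an estimated correlation), with the monocyte marker CD14 at 3.17 ± 0.22, and CD14 stood at 16 ± 0.55 CPM with panobinostat alone and 13.7 ± 1.6 CPM with the combination.

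Against sanguinarine alone, the combination with panobinostat had 7537 genes higher and 6655 lower, with SYT11 at 8.61 ± 0.23 (adjusted p = 1.14e-16, edgeR), CYP1A1 at 5.89 ± 0.25 and MYC at −2.63 ± 0.09. Mitochondrial mRNAs were higher in 13 of 13 cases (13 adjusted over the list alone, median 1.02, adjusted p = 8.58e-05, adjusted p = 0.399 with an estimated correlation), with COX1 at 1.48 ± 0.13. The p53 list was higher in 1, lower in 19 and not passing in 4 of 24 cases (1 and 19 adjusted over the list alone, adjusted p = 4.83e-06). Blood cell markers were higher in 5 of 6 cases and 1 did not pass (5 adjusted over the list alone, adjusted p = 0.0321, adjusted p = 0.399 with an estimated correlation), with CD14 at 3.05 ± 0.21. HMOX1 had a value of −0.20 ± 0.10 (adjusted p = 0.0794).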

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

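Among the tests used here, the comparison of JQ1 with panobinostat, the count of genes that moved alike under both and the tests on overlapping genes were chosen after the result was seen, and the others before the data were examined. The interaction results below stand out because a tested interaction was called, on the log2 scale, between sanguinarine and a partner drug. Cells with and without a partner drug stood in different tables, so a table difference in the effect of sanguinarine cannot be told apart. For some of the called genes the value is no measure of a differing effect, as given below.

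With JQ1 the interaction called 4025 genes (6427 in a fit of only the groups compared). The largest upward departures were MMP1 at 5.94 ± 0.36, SPRR2A at 5.78 ± 1.13, BCL2A1, an anti-apoptotic BCL2 relative, at 5.44 ± 0.54, ARMCX5-GPRASP2 at 5.08 ± 1.66 and the hair keratin-associated gene KRTAP2-3 at 4.68 ± 0.51. The largest downward departures were KRT13 at −4.83 ± 0.41, the glucose transporter SLC5A2 at −4.02 ± 0.95, TMEM59L at −3.58 ± 0.49, the tropomodulin gene TMOD1 at −3.22 ± 0.59 and TP53INP1 at −2.84 ± 0.17. KRT13 stood at 34.3 ± 0.24 CPM with JQ1 and 0.335 ± 0.17 CPM with the combination, and BCL2A1 at 0.168 ± 0.1 and 8.32 ± 4 CPM. BCL2A1 was 6.22 without JQ1 2 and 4.82 without sanguinarine and JQ1 1, KRT13 was −4.09 without sanguinarine 1 and −5.43 without sanguinarine and JQ1 1, and KRTAP2-3 was 3.93 without sanguinarine and JQ1 1. TMEM59L was −4.23 without control 1 and TMOD1 −3.99 without control 2. SPRR2A lost its call without control 1 (4.86, adjusted p = 0.102) and was 6.45 without control 2, and SLC5A2, with 0 and 1 counts in the control libraries, was −3.30 without control 1 and −6.48 without control 2. ARMCX5-GPRASP2 had 0 counts in the sanguinarine libraries, so its fitted value is no bound. It was 5.71 without control 1 and 3.53 without control 2, and its adjusted p was 0.0577 without JQ1 1, 0.0659 without JQ1 2, 0.333 without control 2, 0.133 without sanguinarine 1, 0.143 without sanguinarine 2, 0.0665 without sanguinarine and JQ1 1 and 0.0607 without sanguinarine and JQ1 2.

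With panobinostat the interaction called 3686 genes (2167 without control 1, 2277 without sanguinarine 1, 2349 without sanguinarine 2, 2128 without panobinostat 2 6345 without sanguinarine and panobinostat 2 and 2154 in a fit of only the groups compared). The largest upward departures were CYP1A1 at 4.32 ± 0.36, CYP1B1 at 3.43 ± 0.28, TNC at 3.19 ± 0.21, SPRR2A at 3.14 ± 0.96 and MEF2B at 2.99 ± 0.78. The largest downward departures were the TNF family ligand CD70 at −6.12 ± 1.55, SAA2-SAA4 at −5.49 ± 1.76, AKR1C1 at −5.07 ± 0.26, SLC5A2 at −4.27 ± 0.93 and CLDN16 at −4.23 ± 0.72.

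Several of these calls rested on few reads. CD70 and SAA2-SAA4 had 0 counts in the control, so their fitted values are no bounds, and CD70 had an adjusted p of 0.053 without control 1, 0.0718 without control 2 and 0.0632 without sanguinarine 1. SAA2-SAA4 had 0.119 without control 1, 0.152 without control 2, 0.0696 without panobinostat 2, 0.132 without sanguinarine 1 and 0.0576 without sanguinarine 2. MEF2B was 1.98 without control 1 (adjusted p = 0.299), 3.67 without control 2 and 2.64 without sanguinarine 1 (adjusted p = 0.074). SPRR2A was 2.22 without control 1 (adjusted p = 0.421) and 3.80 without control 2, and had an adjusted p of 0.0696 without panobinostat 2, 0.0605 without sanguinarine 1 and 0.0524 without sanguinarine 2. SLC5A2 was −3.55 without control 1 and −6.73 without control 2.

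The tables were counted differently over overlapping genes, and such a difference need not cancel in an interaction. SAA2-SAA4 and ARMCX5-GPRASP2 are readthrough genes that overlap others. SAA2-SAA4 stood at 0 in the control, 0.0975 ± 0.031 CPM with sanguinarine, 129 ± 9 CPM with panobinostat and 123 ± 20 CPM with both, and ARMCX5-GPRASP2 at 0.0672 ± 0.062, 0, 6.55 ± 0.031 with JQ1 and 7.27 ± 0.25 CPM with both. Their interaction values are therefore no measure of a differing effect of sanguinarine. MMP1, KRT13, SLC5A2, TMOD1 and MEF2B also overlap another gene.

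In the second table, titles beginning with S- carry labels of a partner drug alone, and the other titles carry the combination labels. Had the labels been exchanged, the change from partner to combination would have run against the change from control to sanguinarine. Across genes the correlation was instead 0.21 for JQ1 and 0.189 for panobinostat (SD over single-library pairs 0.03 and 0.021), which argues against an exchange in either pair. HMOX1, at 212 ± 24 CPM with sanguinarine, stood at 689 ± 21 and 207 ± 17 CPM in the libraries labelled as combinations, and at 9.73 ± 0.18 and 8.89 ± 0.13 CPM in those labelled as partner drugs alone.

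Most tested genes differed between the drugs of the second table and the control, 60.9% with JQ1 and 66.1% with panobinostat. With DESeq2 size factors 13559 genes were called for JQ1, against 13555 with TMM, which met a bound set beforehand against scaling. Both methods assume that most genes do not change, so this cannot decide whether scaling had a part. Counting of reads over overlapping genes may account for the 164 genes with no counts in the first table, all of which overlap another gene, but not for genes that overlap none, of which 59.6% changed with JQ1 and 65.2% with panobinostat. An offset shared by the second table cancels between JQ1 and panobinostat, so for the 55.9% of tested genes that differed there it is argued against as the whole cause under both drugs, while its part in the change under either drug stays open. For the 4117 genes that moved alike under both drugs and did not differ between them, drug and batch cannot be told apart, because the control was only in the first table.

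Mitochondrially encoded mRNAs were lower with sanguinarine, with a median of −2.01 on the log2 scale. Their median was −2.03 with DESeq2 size factors, which met a bound set beforehand against scaling. Both methods assume that most genes do not change, so this cannot decide the question. Scaling moves all genes of a library alike, however, and 48 nuclear respiratory chain genes had a median of −0.25 (SD 0.13). That gap argues against scaling as the whole cause, and against an equal fall of respiratory chain transcripts from both genomes. A weaker uptake in poly(A) selection stays open. The ribosomal RNAs RNR1 and RNR2 had log2 changes of −2.37 ± 0.14 and −1.25 ± 0.10, which met a bound set beforehand against it, but every library was selected on poly(A), so the ribosomal RNAs read here also came through a tail and the explanations cannot be told apart. An effect of sanguinarine on mitochondrial transcripts, which the design names as a group difference, was not tested apart from this.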

How the results depend on the processing

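The fits of only the libraries of a table, the fits of only genes that overlap no other gene, the split of the controls and all alternatives for JQ1 against panobinostat were chosen after seeing the data, and the others before. With DESeq2 size factors and without a low-count filter, all 17 counts of changed genes stayed within 1.5 times. With the DESeq2 Wald test 16 of 17 did, the exception being cepharanthine with 1243 genes, and the cause was not tested. Size factors gave 209 passing lists against 214, with no change of direction. The share of called genes that were higher crossed 50% with size factors in some comparisons. It went from 53.2% to 48.9% for sanguinarine and from 55.2% to 49% for sanguinarine against evodiamine. For sanguinarine with panobinostat against panobinostat it went from 50.1% to 48.6%, and for the interaction with panobinostat from 47.7% to 50.8%. Of the named and called genes, 68 of 76 for sanguinarine, 33 of 55 for cepharanthine, 48 of 56 for evodiamine, 90 of 97 for sanguinarine with JQ1 against JQ1 and 43 of 61 for sanguinarine with panobinostat against panobinostat kept their call under every alternative run, and none reversed in any comparison.

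A fit of only the groups compared gave 8741 genes for sanguinarine, 2640 for cepharanthine, 6018 for evodiamine, 5998 for sanguinarine against cepharanthine, 8225 against evodiamine, 5193 for cepharanthine against evodiamine and 6427 for the interaction with JQ1. It gave fewer, 1772, for sanguinarine with panobinostat against panobinostat, and 2154 for the interaction with panobinostat. A fit of only that table gave 7867 for sanguinarine, 3175 for cepharanthine, 5585 for evodiamine, 6563 for sanguinarine against cepharanthine, 7691 against evodiamine, 6233 for cepharanthine against evodiamine and 3135 for sanguinarine with panobinostat against panobinostat. The cause was not tested.

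Over the 9617 tested genes that overlap no other gene, where fewer genes could be called, counts against control were 2429 for sanguinarine, 400 for cepharanthine, 1296 for evodiamine, 5735 for JQ1, 6273 for panobinostat, 5949 for sanguinarine with JQ1 and 6648 for sanguinarine with panobinostat. Against the partner they were 3167 with JQ1 and 2429 with panobinostat, and against sanguinarine 5418 and 6122. The others were 1682 for sanguinarine against cepharanthine, 2305 against evodiamine, 1536 for cepharanthine against evodiamine, 1876 and 1704 for the interactions with JQ1 and panobinostat, and 5735 for JQ1 against panobinostat.

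Leaving out each replicate in turn, where a lone library is assumed to vary like the other groups, gave 2665 to 2815 genes for sanguinarine, 352 to 404 for cepharanthine, 1076 to 1255 for evodiamine, 1312 to 1932 for sanguinarine against cepharanthine, 2252 to 2684 against evodiamine and 1467 to 1656 for cepharanthine against evodiamine. It gave 2068 to 7836 for sanguinarine with panobinostat against panobinostat and 2128 to 6345 for the interaction with panobinostat. The other counts stayed within 1.5 times, at 4513 to 5218 for sanguinarine with JQ1 against JQ1, 2687 to 3478 for the interaction with JQ1, 11915 to 12139 for JQ1, 13022 to 13272 for panobinostat and 10330 to 10829 between them. Against control they were 12270 to 12691 for sanguinarine with JQ1 and 13639 to 15184 for sanguinarine with panobinostat, and against sanguinarine 11140 to 11670 and 12358 to 14189. The cause was not tested, and the gene lists were not tested without single libraries.

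A replicate block from the title numbers gave 5448 genes for sanguinarine with JQ1 against JQ1, 3738 for sanguinarine with panobinostat against panobinostat and 11667 for JQ1 against panobinostat. All were within 1.5 times of the main counts. The block was fitted to the second table alone, whereas the main counts come from all libraries, so the block is not the only difference. Deviations of equally numbered replicates correlated across genes at −0.032 to 0.085, so no shared effect of the numbers was seen. That cannot show whether the libraries were prepared in pairs. No paired analysis was possible for the other comparisons, because the titles of the first table carry running numbers that no other group shares.

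With an estimated correlation 78 of the 214 list calls stood, and the cause was not tested. The correlation of the sanguinarine response with the combination was 0.501 over called genes and 0.371 over genes of at least 5 CPM for JQ1, and 0.425 and 0.276 for panobinostat. At an adjusted p under 0.01, sanguinarine and cepharanthine shared 216 higher and 51 lower genes, sanguinarine and evodiamine 296 and 262, and cepharanthine and evodiamine 97 and 16, as a stricter threshold calls fewer genes. The pseudocount alternative was not run, because the files hold counts. Depth limits genes near the floor of 0.0468 to 0.075 CPM per library, where folds against control rest on few reads.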

Other observations

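NEUROD1, a neuroendocrine transcription factor of small cell lung cancer, had 0 counts in all 16 libraries, which allows up to 0.0468 to 0.075 CPM per library. The granule protein gene CHGA had group means of 0.0957 to 0.628 CPM. YAP1, a transcriptional regulator of non-neuroendocrine cells that was chosen after its values were seen, stood at 266 ± 1.7 CPM in the control, 290 ± 7 CPM with sanguinarine, 195 ± 5.7 CPM with JQ1 and 115 ± 0.24 CPM with panobinostat. DLL3, an inhibitory Notch ligand of neuroendocrine tumours, stood at 0.935 ± 0.38 CPM in the control and 3.35 ± 0.28 CPM with panobinostat. SYP, a synaptic vesicle gene that overlaps another gene, stood at 0.299 ± 0.0024 CPM in the control and 18.9 ± 1.8 CPM with panobinostat. For YAP1, DLL3 and SYP alike, table and drug cannot be told apart between the control and JQ1 or panobinostat. The lists of non-neuroendocrine regulators and of the BCL2 family passed in none of the 17 comparisons.

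Further genes were compared between the combinations and the partner drugs. Against JQ1 alone, the metallothionein genes MT1E, MT1X and MT2A, which bind metals and are close in sequence, were higher by 2.40 ± 0.12, 2.40 ± 0.17 and 1.69 ± 0.13. Immediate early genes were higher in 14, lower in 2 and not passing in 10 of 26 cases (14 and 2 adjusted over the list alone, camera adjusted p = 7.67e-05, adjusted p = 0.181 with an estimated correlation), with the ETS factor ETV4 at 2.39 ± 0.13 and EGR1 at 1.95 ± 0.15. Neuroendocrine genes were higher in 7 of 18 cases and 11 did not pass (7 adjusted over the list alone, adjusted p = 0.00257, adjusted p = 0.159 with an estimated correlation), with UCHL1, a neuronal ubiquitin hydrolase, at 1.13 ± 0.09. Against panobinostat alone, heat shock genes were lower in 10 of 20 cases and 10 did not pass (10 adjusted over the list alone, adjusted p = 0.000169, adjusted p = 0.264 with an estimated correlation), with HSPA8 at −0.67 ± 0.09.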
